A study of Homo sapiens with 2 samples.

How the data were processed

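Gene expression was measured in SiHa cells, a human papillomavirus-positive cervical carcinoma line, on one-colour Agilent microarrays, which carry short DNA probes that capture Cy3-labelled copies of the cells' RNA. Per the labels, stable lines were made with a lentiviral system carrying a SLUG or a control plasmid, and 1 array was run from each line. Samples were grouped by the genotype in the labels. The design gives 1 array for the control and 1 for SLUG overexpression. There is no replicate, so no p-value, standard error or count of significantly changed genes can be had, and the number of arrays limits the precision of every value.

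The submitters' processing notes name Agilent Feature Extraction 10.7 and limma, without saying what each did. The background correction, the filter on dim spots and the treatment of repeated spots are not given in the sources used here. The deposited value table holds 1 log2 signal per probe and array for 58341 probes. The log base is not stated in it. It was inferred to be log2 because a difference of at least 1, with a higher value of at least 7, gave 126 probes, the total in the authors' deposited table of counts at a 2-fold threshold with the mark "mean7". The sorted values of the arrays differed by a median of 0.00352 and by at most 0.137, with the same minimum (-0.0291) and maximum (17.0), as they would after quantile normalization by the authors. Such a normalization forces equal distributions, so a change in total RNA output cannot appear as a shift of the bulk of the probes. The values were used as deposited. The authors' table of counts gives numbers of genes past a fold threshold, with the p-value threshold left empty.

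The deposited files used here do not pair the probe IDs with genes. None of the 58201 sample probe IDs matched an entry in the reference gene table, which lists symbols, synonyms and RefSeq and Ensembl accessions (0 matched). The gene-level analysis fixed before the data were examined could therefore not be run: 35 gene lists, the named genes of the study's title, the summary of several probes per gene and the agreement of probes of one gene. All results are per probe. At most 2 probe IDs per direction are printed, the extremes of the rule for named genes (largest differences among probes whose mean signal is at or above the median) applied to probes. The RNA of the overexpressed gene was not checked for the same reason, so the labels rest on the submitters' word.

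Probes were sorted by their ID. There were 58201 sample probes (IDs starting with A_), 10 E1A spike-in probes, 18 DCP probes, 96 ERCC probes, 13 ETG probes and 3 others, 2 of them corner spots. E1A spike-ins are viral transcripts of known amount that Agilent's labelling kits can add to the RNA. ERCC probes match an external set of spike-in transcripts whose use is not stated in the labels. The filter fixed before the data were examined kept probes with a mean of both values at or above the median of all values, 2.30. Probes were also counted where either value reached 7 (called bright below). This filter was inferred from the total of 126 after the data were seen. The authors' mark "mean7" read as a mean of both values of at least 7 gave 88 probes. Differences are the SLUG overexpressing value minus the control value on the log2 scale. A value under the 95th percentile of the ERCC probes on its array (2.45 for control, 2.88 for SLUG overexpression) was treated as not above background, and the fold against it was computed from that percentile as a lower bound. This background rule was chosen after the data were seen. For the E1A and DCP probes, above background meant instead a mean log2 signal over 1, and unsaturated meant both values under 16.

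Alternatives were other filters, median centring, quantile normalization, lowess centring (span 0.3, 3 passes), centring on the spike-ins and an offset of 50 on the linear scale. The last 2, and all alternatives for the bright probes, were chosen after the data were seen. Spike-ins were compared with 10000 random sets of sample probes, each probe within 0.25 of a spike-in's mean signal. Counting and lowess centring were tested on simulated data for this comparison: 200 bright probes among 58201 were changed 4-fold, 100% were recovered, and 2 unchanged bright probes were called higher and 0 lower. A 4-fold change lies far past the 2-fold limit, so recovery was nearly assured. The simulated noise was normal and calls were made after lowess centring. The 2 false calls are therefore no error estimate for the counts reported from the deposited values. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.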

Results

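SLUG, encoded by SNAI2, is a zinc-finger transcription factor known for repressing E-cadherin and for its part in epithelial-mesenchymal transition. The series compared SiHa cervical carcinoma cells that stably overexpress SLUG with control SiHa cells, to find genes whose expression differed. Its title also names MMP3, a secreted metalloproteinase (stromelysin) that degrades extracellular matrix, as a direct target. The data were 1 array of control cells and 1 array of SLUG overexpressing cells, each with a normalized log2 signal for 58201 sample probes. No replicate of either group was measured, so each difference below is between 2 single arrays and carries no error between cultures. Values for SNAI2, MMP3 and other named genes are not reported, because the probes were not paired with genes here.

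Both arrays held nearly the same distribution of signals. The median over all probes was 2.31 in control cells and 2.30 in SLUG overexpressing cells, and 12049 and 12035 sample probes, respectively, reached a log2 signal of 7. The dark corner spot, which carries no target sequence, read 0.41 and 0.42. Of the sample probes, 49.1% in control cells and 45.9% in SLUG overexpressing cells lay above the 95th percentile of the ERCC probes on the same array. As the distributions were nearly equal, this gap reflects the unequal limits, 2.45 for control and 2.88 for SLUG overexpression. It does not show that fewer RNAs were detected in SLUG overexpressing cells. Across the sample probes the arrays correlated with Pearson's r = 0.986 and Spearman's rho = 0.930. This is a correlation across probes, which are not independent replicates.

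Relative to the bulk of the probes, most probes with a clear signal differed little between the control and the SLUG overexpressing array. Of the 12437 bright probes, those with a signal of at least 7 on either array, 99.0% differed by less than 2-fold. The median difference, SLUG overexpressing minus control, was -0.02 and the central 90% of the differences ran from -0.44 to 0.48 on the log2 scale. The nearly equal distributions bring this median near 0 by construction. Among the bright probes, 98 were at least 2-fold higher in SLUG overexpressing cells and 28 were at least 2-fold lower, so 77.8% of the 126 were higher. The authors' deposited table gave 126 genes in a 2-fold line marked "mean7", and listed 28 as up and 98 as down. The log base and the use of either value were inferred from that total, so the match of totals is no independent check. The split was not part of that inference, and it gave the authors' 2 numbers with the directions exchanged. Read as a mean of both values of at least 7, the mark gave 88 probes, 68 higher and 20 lower. The direction used here, taken from the sample labels, is under either reading the opposite of the one in that line of their table.

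At 3-fold, 15 bright probes were higher and 2 lower, and at 4-fold 9 were higher and 0 lower. Without a filter on signal the directions were nearly balanced at each fold, with 50.6% higher at 2-fold, 50.8% at 3-fold and 50.5% at 4-fold. With both values at 7 or above, 52 probes were at least 2-fold higher and 15 lower. In that set the largest positive difference was a probe at 7.48 in control and 10.1 in SLUG overexpressing cells, 6.19-fold apart, and the largest negative one a probe at 8.69 and 7.04, 3.16-fold apart. These values are relative to the bulk of the sample probes. The E1A spike-ins were 0.38 higher on the SLUG overexpressing array. Relative to them, the bright probes split into 33 higher and 188 lower, so 14.9% were higher and the tilt was the opposite one. Subtracting 0.38 from differences centred near 0 moves the split toward lower probes by construction. The spike-ins are a fair reference only if equal amounts entered both samples, which is not known here.

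**Figure D1:**
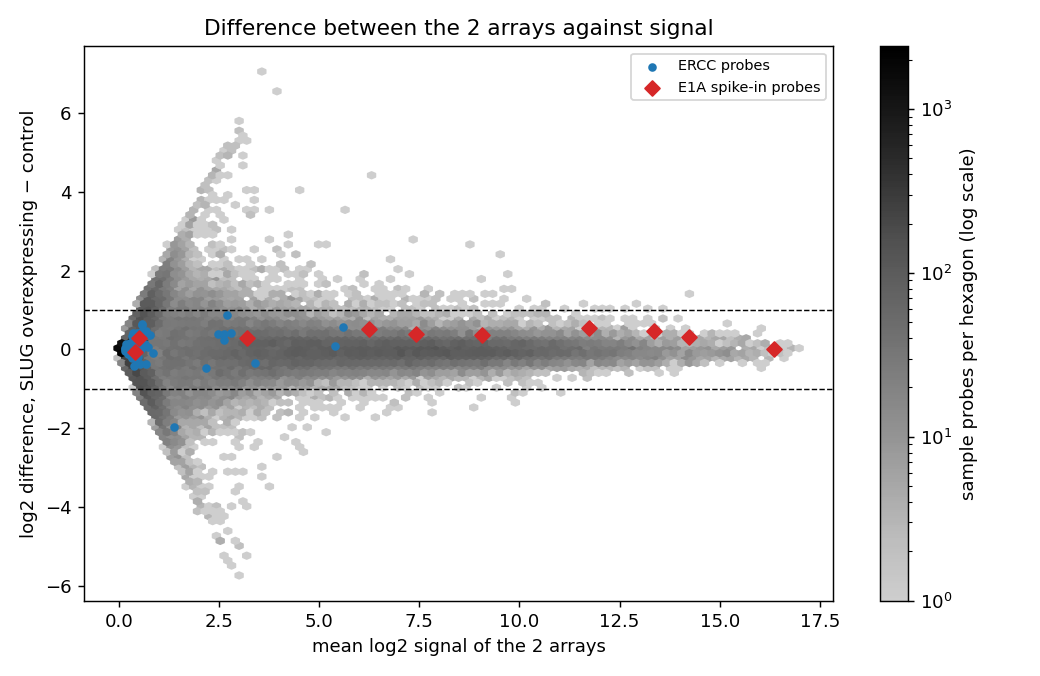
Log2 difference, SLUG overexpressing minus control, of each probe against its mean log2 signal on the 2 arrays; grey hexagons count sample probes on a log scale, red diamonds are the 10 E1A spike-in probes, blue points the 96 ERCC probes and dashed lines mark a 2-fold difference. The cloud is tight near the floor, widest at a mean signal from 1 to 3 and narrower as signal rises from there, and 7 unsaturated spike-ins above background lie at 0.28 to 0.54.

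With the filter fixed before the data were examined, a mean signal at or above the median of 2.30, 28819 sample probes were measured. Of these, 644 were at least 2-fold higher and 463 at least 2-fold lower in SLUG overexpressing cells, and 96.2% differed by less than 2-fold. At 4-fold, 113 were higher and 58 lower. Many of these differences involved a signal under the ERCC limit on one array. That limit lies above most ERCC probes, of which 86 of 96 in control and 87 in SLUG overexpression read under 1. A value under the limit is therefore not always at the floor. The control value was under the ERCC limit for 295 of the 644 higher probes (45.8%), and the SLUG overexpressing value was under it for 311 of the 463 lower probes (67.2%). Among bright probes this held for 2 of the 98 higher and 0 of the 28 lower probes. The limit was 2.45 for control and 2.88 for SLUG overexpression, and the higher limit can raise the share among lower probes. The shares of higher and lower probes are therefore not directly comparable. Relative to the spike-ins, the measured probes split into 291 higher and 1631 lower, so 15.1% were higher in place of 58.2%. Subtracting the spike-in median brings a move in that direction by construction. With an offset of 50 added to the linear signals, 63 measured probes were at least 2-fold higher and 14 at least 2-fold lower. Probes whose higher value is under 5.70 drop out of this count by construction.

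The share of probes with a 2-fold difference depended on signal. It was 8.42% of the 23102 probes with a mean signal under 1, where both values lie near the floor, and 34.5% of the 9045 probes with a mean signal from 1 to 3, 5.53% of those from 3 to 5, 1.92% from 5 to 7, 0.959% from 7 to 9 and 0.286% of the 700 probes from 13 to 17. The robust SD of the differences was 1.01 from 1 to 3 and 0.20 from 13 to 17. From 5 to 7, 83 probes were higher and 41 lower, and from 7 to 9, 44 were higher and 12 lower. From 1 to 3 the directions were nearly balanced, with 1538 higher and 1578 lower.

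**Figure D2:**
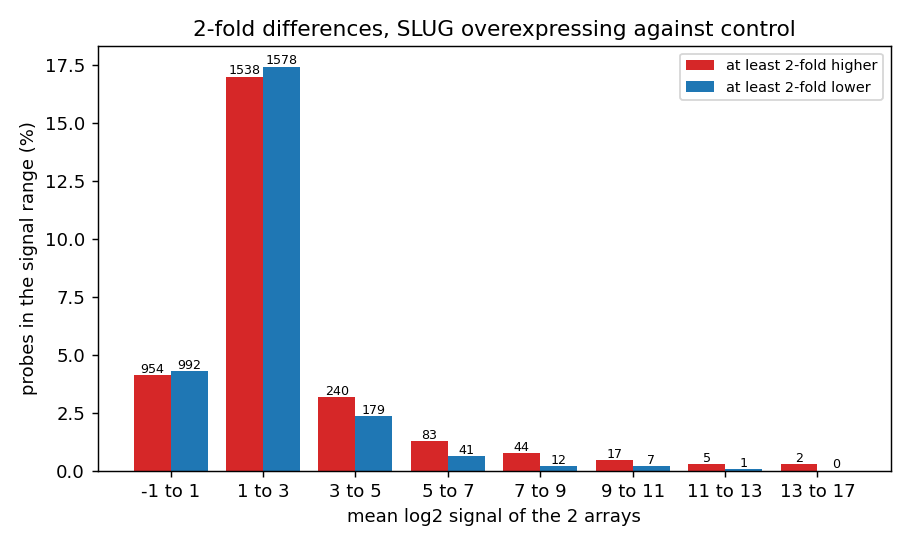
Percentage of sample probes at least 2-fold higher (red) or lower (blue) in SLUG overexpressing cells, by the mean log2 signal of the 2 arrays; the number over each bar is the count of probes. Below a mean signal of 3 the directions are nearly balanced, and from 3 upward higher probes outnumber lower ones in each range.

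The largest differences were between a clear signal on one array and a background signal on the other. Probe A_22_P00022906 read 7.17 in SLUG overexpressing cells and 0.12 in control cells, which is not above background, so it was at least 26.4-fold higher. Probe A_21_P0013114 read 7.17 against 0.63 and was likewise at least 26.4-fold higher. In the other direction, probe A_22_P00010297 read 5.92 in control cells and 0.18 in SLUG overexpressing cells, at least 8.21-fold lower. Probe A_22_P00017941 read 5.54 against 0.08, at least 6.32-fold lower. The dim value lay under the ERCC limit in all 10 of the highest and all 10 of the lowest differences among the measured probes. The bounds hold on the deposited scale. With an offset of 50 added to the linear signals, the differences of these 4 probes were 1.93, 1.91, -1.11 and -0.92 on the log2 scale, all smaller than the bounds, and that of A_22_P00017941 was under 2-fold. Each probe was read once per group, and no replicate check of these differences exists.

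The authors' deposited table listed 1904 genes past a 2-fold threshold, 1012 up and 892 down, and 842 past a 3-fold threshold, 463 up and 379 down. The value table gave 5693 sample probes at 2-fold without a filter, 2883 higher and 2810 lower in SLUG overexpressing cells. At 3-fold it gave 1845, of which 937 were higher and 908 lower. The filter behind the authors' smaller totals is not given in the sources used here.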

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

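The tests in this part were chosen after the counts in the report were seen. For the lowess and offset tests on the bright probes, the bounds were written down before those tests were run. The E1A spike-in probes stood out because they are control spots outside the comparison of sample probes and yet differed between the arrays. Their median difference was 0.38 on the log2 scale (1.30-fold, SD 0.103 over 7 unsaturated probes above background), higher on the SLUG overexpressing array in 7 of 7. The 13 unsaturated DCP probes above background were also all higher there, with a median of 0.34. Sample probes matched on signal had a median difference of -0.0258, and 24 of 10000 matched random sets reached 0.38. Equal distributions on both arrays fix such a median near 0, so these values do not decide on a bias that depends on signal. A candidate explanation is more spike-in per labelled sample on one array, which predicts one factor at all amounts, and the SD of 0.103 over spike-ins from 3.05 to 14.1 in control signal is in line with it. Whether that reflects pipetting, labelling yield or RNA content of the cells was not tested, and no biological explanation was tested.

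Bright probes that were at least 2-fold higher (98) outnumbered those that were lower (28). Probes near the floor of one array do not account for it, since 77.6% were higher when both values had to reach 7. Lowess centring left 78.9% higher, but it moved almost nothing on arrays already brought to one distribution (125 of the 126 probes were shared). The median differences were -0.0155 at a mean signal from 7 to 9, -0.0189 from 9 to 11, -0.00496 from 11 to 13 and -0.0381 from 13 to 17. For probes with a mean of at least 7, they show little signal-dependent offset of the bulk left in the deposited values. Equal distributions bring such medians near 0 by construction. A bias present before the authors' normalization cannot be seen in these values. A difference between single cultures or arrays that has nothing to do with SLUG cannot be told apart from an effect of SLUG, because the design has 1 array per group. The tilt is also defined only relative to the bulk of the sample probes. Relative to the spike-ins the split was 33 higher and 188 lower, a move that subtracting the spike-in median brings by construction.

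Most 2-fold differences, 5567 of 5693 (97.8%), were in probes under 7 on both arrays. A candidate explanation is that a log scale without an offset spreads signals near background. An offset of 50 brought 99.8% of these dim probes under 2-fold, but also 46.8% of the 126 bright ones, more than the bound of 25% set before the test was run. For the 5472 dim probes with a higher value under 5.70 the offset leaves no 2-fold difference by construction, so the test does not decide, and only repeated arrays could separate noise from change in these probes.

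Among the 96 ERCC probes, 2 read 5 or more on the SLUG overexpressing array and 2 on the control array, against an ERCC median of 0.37 and 0.30. They stood out as signal in spots outside the main measurement.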

How the results depend on the processing

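The counts depended on the filter on dim probes. Against 644 higher and 463 lower probes with a mean signal at or above the median, no filter gave 2883 and 2810, either value at or above the median gave 1215 and 1093, and a mean at or above the 75th percentile (6.19) gave 98 and 30. Fewer or more probes enter by construction. Median centring (667 and 451), quantile normalization (646 and 459) and lowess centring (665 and 452) stayed within 1.5 times, and of the 126 bright probes 125, 124 and 125 were shared. On arrays already brought to one distribution such scalings can move little by construction. These counts therefore do not show stability against normalization. The counts of bright probes and the settings that follow were chosen after seeing the data. Centring on the spike-ins gave 291 and 1631 measured probes and 33 and 188 bright ones, sharing 61 of the 126. Subtracting one positive constant from all differences brings this move toward lower probes by construction. An offset of 50 gave 63 and 14 measured and 54 and 13 bright probes, with 81.8% of the measured ones higher. It leaves no 2-fold difference where the higher value is under 5.70, so it acts much like a filter on signal. The 81.8% therefore mostly repeats the split of the bright probes. Both values at 7 or above gave 52 and 15, and a mean of at least 7 gave 68 and 20. Under the offset the 4 named probes differed by 1.93, 1.91, -1.11 and -0.92. The other 4 scalings can shift them little by construction and say nothing about their stability. The spike-in median was between 0.32 and 0.40 under 4 scalings, with 0.32 under the offset. Median centring, quantile normalization and lowess centring can move it little by construction. The alternatives set beforehand for several probes per gene, gene lists and probe agreement were not run, as no probe was paired with a gene, and the pseudocount was not needed for log values. No paired analysis was possible because each group has 1 array, and no replicate can be left out. Signal near background limits the precision of dim probes.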

Other observations

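The authors' deposited table and the value table can be set against each other for direction. These comparisons were chosen after the counts were seen. In the line marked "mean7", 28 up and 98 down mirrored the 98 probes higher and 28 lower in SLUG overexpressing cells. In the other lines of the table the tilt ran the opposite way from that line, with 1012 up against 892 down at 2-fold and 463 up against 379 down at 3-fold. Among filters on the higher value of each probe, the one nearest to those totals, at least 2.55, gave 1013 higher and 850 lower in SLUG overexpressing cells at 2-fold, and 448 higher and 370 lower at 3-fold. On the deposited scaling, 0 of 920 nested lower limits on signal gave fewer higher than lower probes. Limits were used where at least 20 probes passed the fold threshold. They pool 2-fold and 3-fold counts and limits on the higher, mean and lower value, so they overlap and are not separate checks. Single signal ranges gave fewer higher than lower probes (1538 higher and 1578 lower from a mean of 1 to 3). So did centring on the spike-ins (291 higher and 1631 lower). For the line marked "mean7" the recount of probes gave the authors' total and their split exchanged. Up in that line thus matched lower in SLUG overexpressing cells under the inferred filter. The authors' table labels its counts as genes, although the recount of probes reached the total of the marked line. For the other lines the filter is unknown. The direction used in those lines is therefore not settled here.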
